A study of Marchantia polymorpha and Klebsormidium nitens with 56 samples.

How the data were processed

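RNA sequencing libraries of the liverwort *Marchantia polymorpha* and of the streptophyte alga *Klebsormidium nitens* were compared with and without heat. Gemmalings are the young plants that grow from gemmae, the vegetative propagules of the liverwort. Per the labels they were 7 days old and had grown under continuous light at 22 °C, heat was 37 °C, and *K. nitens* was one month old and heated for 2 h. RNA was extracted with the RNeasy Plant Mini Kit and sequenced on a NovaSeq instrument. The accessions Tak-1 (male), Tak-2 (female) and BC3 (female) are wild types. The growth text names HSFA1 overexpression lines and knockout mutants of HSFA1 and HSFB1, which are genes of heat shock transcription factors. The 4 chromatin immunoprecipitation samples of the series were not analysed here.

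The deposited tables hold counts of reads per gene as whole numbers, with no normalization, and each library was matched to its column through the labels and the sample sheets. The submitters' processing notes name STAR as the aligner. Its version, the program that counted reads and the genome builds are not given in the sources used here. Strandedness, the handling of reads that map to several genes and the removal of duplicate reads are likewise not given in the sources used here, and each could change counts of gene families such as histones and heat shock proteins. Values compare only within a table, because the tables use different gene identifiers.

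The first table held 28 *M. polymorpha* libraries in 14 groups of 2, the second 18 libraries in 9 groups of 2, and the third 6 *K. nitens* libraries in groups of 3. One identifier present more than once in the first table was summed, which left 20574 genes. A line without a name in the second table equalled the column sums and was left out, which left 19755 genes, and the third table held 16122 genes. Gene symbols for the first table came from a reference that pairs locus tags with symbols. Of its 20574 genes, 17641 matched a locus tag and 3091 had a symbol, of which 2351 were tested. The match was checked by the Spearman correlation of gene length with expression, which was 0.242 for the match used and at most 0.038 for matches shifted by up to 5 genes. Chromosomes are given as the identifiers write them (Mp1g for chromosome 1, MpVg for the V chromosome of males). The first table held 207 V-linked identifiers and 0 from the U chromosome of females. The reference used here gives no symbols for the identifiers of the other tables.

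Counts were tested in R 4.3.3 with edgeR 4.0.16 by the quasi-likelihood F test, with TMM scaling and the filterByExpr rule for low counts, in a model with a mean for each group of a table. This left 13432 genes in the first table, 10832 in the second and 11387 in the third, which hold 99.98%, 99.97% and 99.99% of the reads. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p below 0.05 were counted as higher or lower. Comparisons were heat against control in each genotype, each mutant or overexpression line against its wild type without heat, 5 h against 1 h of heat, and the difference in heat response between genotypes (the interaction). Levels are in CPM (reads scaled by library total and TMM factor) as mean ± SD, n = 2 libraries in *M. polymorpha* and n = 3 in *K. nitens*. Changes are log2 fold changes ± SE from the edgeR fit. The design text of the series calls the replicates biological, and the p-values measure the spread between libraries.

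Comparisons, tests, the threshold, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes the 8 highest and 8 lowest changes among named genes of at least 5 CPM in each heat comparison, 4 and 4 in the others, and 2 identifiers in each direction where no symbols exist. The subjects of 22 gene lists were fixed at the same time, but 9 match no symbol and the matching patterns were written after the symbols were seen. The patterns of the peroxidase list and of several others were added after fold changes had been seen. List p-values may therefore be shaped by the data they test. The 13 lists with symbols are HSP90, heat shock factors, antioxidant enzymes, LEA proteins, abscisic acid signalling, phenylpropanoid enzymes, chlorophyll synthesis, histones, cell cycle, cell wall, reproductive regulators, peroxidases and endoplasmic reticulum folding. Of these, 10 had at least 4 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and again with an estimated correlation. Estimates ran from -0.0224 for reproductive regulators to 0.566 for histones, with 0.390 for HSP90 and 0.391 for cell cycle genes. Where the estimate is far above the preset, the preset can make p-values too small. A further 26 families of at least 20 symbols were added after the data were seen. Examples outside the rule for named genes were also chosen after their values were seen. Sets of heat-responsive genes, at least 2-fold up or down (log2 of 1) in one wild type of the first table, were tested only in comparisons that use none of its libraries. These sets replaced the planned ones from the second table, whose identifiers differ.

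Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a fit to only the groups compared, replicate numbers as a block, and leaving out each library in turn. Leaving out a pair of doubted control libraries of the second table was added after the data were seen. The tests were also tested on simulated counts, drawn from the mean control level, library sizes and trend of spread with level of each table. Known changes were added to a few genes of a single group, while Tak-1 heat called 51.1% of genes in the real data. The rates that follow therefore need not hold for the real libraries. For Tak-1 heat, edgeR found 71 of 95 genes changed by a log2 of 1 and 92 of 100 changed by a log2 of 2, and 7.39% of its calls were false. For the interaction of hsfa1y it found 63 of 95 and 89 of 100, with 4.40% false. In *K. nitens* it found 97 of 100 and 100 of 100, with 7.08% false. With 2 libraries per group, a gene that did not pass may still differ. Where a group had 0 reads of a gene, the fold change is given as at least the ratio to a floor of 3 counts per library. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.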

Results

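Transcript levels were measured by RNA sequencing in whole gemmalings of *M. polymorpha* and in plate cultures of *K. nitens*, with and without heat at 37 °C. The first experiment held 28 libraries in 14 groups of 2. Control and heat libraries came from Tak-1 (male wild type), BC3 (female wild type) and the lines titled hsfa1y and hsfb1 (male background) and hsfa1x (female background). Plants overexpressing HSFA1X or HSFA1Y in each background had control libraries alone. Each library held 17.7 to 23.997 M reads (median 20.1 M), and the 10 most abundant genes took 5.13 to 7.94% of them. The labels of this experiment do not give the hours of heat for each sample. The sample sheet beside the table lists hsfa1x, hsfa1y and hsfb1 as knockouts (xko, yko and bko), apart from the overexpression lines (xox and yox). The genotype field gives "ko" for hsfa1y and hsfb1 but "ox" for hsfa1x, and hsfa1x is taken here as a knockout, as in the sheet. The second experiment held 18 libraries in 9 groups of 2, from Tak-1, Tak-2 and BC3 after 0, 1 and 5 h of heat, with 15.1 to 21.5 M reads (median 17.01 M). The third held 3 control and 3 heat libraries of *K. nitens* with 19.7 to 28.3 M reads (median 23.9 M). Between the libraries of a group, counts varied 2.11 to 36.4 times as much as counting error alone would give (chi-square per degree of freedom over genes with at least 20 reads).

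Of the genes targeted in these lines, none was paired with an identifier by name in the sources used here, so their state was not checked. The only heat shock factor with a symbol was MpHSF1 (Mp4g12230, chromosome 4), a member of the transcription factor family that activates chaperone genes in heat. Without heat its level was 12.9 ± 1.39 CPM in Tak-1, 21.5 ± 3.20 in BC3, 8.42 ± 0.0189 in hsfa1y, 21.2 ± 1.53 in hsfa1x and 73.5 ± 2.67 in hsfb1 (SD, n = 2 here and throughout both *M. polymorpha* experiments). In the overexpression lines it was 25.5 ± 0.815 (HSFA1X in Tak-1), 30.9 ± 2.49 (HSFA1Y in Tak-1), 43.3 ± 1.72 (HSFA1X in BC3) and 28.5 ± 1.02 CPM (HSFA1Y in BC3). With heat it was 44.1 ± 5.04 CPM in Tak-1, 49.3 ± 1.30 in BC3, 11.2 ± 3.04 in hsfa1y, 44.3 ± 3.37 in hsfa1x and 77.6 ± 8.49 in hsfb1.

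The heat response of the male wild type was read from heat against control libraries of Tak-1. Genes of HSP90, the chaperone that folds signalling proteins, rose to high levels. MpHSP90-1 (Mp1g26610) rose from 378 ± 2.41 to 5482 ± 10.8 CPM (log2 change 3.86 ± 0.07 SE, adjusted p = 8.03e-23) and MpHSP90-4 (Mp5g15940) from 179 ± 7.82 to 1991 ± 14.7 CPM (3.47 ± 0.08). MpHSF1 rose by a log2 of 1.77 ± 0.14 (adjusted p = 9.92e-11). MpCNX (Mp4g06370), which encodes calnexin, a folding lectin of the endoplasmic reticulum, rose from 474 ± 15.02 to 1163 ± 10.4 CPM (log2 1.30). Other rises among named genes were those of MpNBS-LRR17 (Mp5g21860), of the family of intracellular immune receptors, at a log2 of 5.01 ± 0.29, MpPKS/CHS13 (Mp4g14180), of the chalcone synthase family, at 4.22, and MpBBX6 (Mp2g16350), a B-box protein, at 3.67. MpLDAP (Mp4g15940), of a lipid droplet protein, rose by 3.51 ± 0.09 and MpOLEOSIN (Mp5g10430) by 3.39. Among the largest falls were those of the transcription factor genes MpBHLH2 (Mp2g00890, log2 -4.76 ± 0.22, adjusted p = 7.84e-15), MpERF21 (Mp5g22160, -4.56) and MpBHLH4 (-4.20) and of the auxin-related MpSAUR14 (-4.58) and MpSAUR12 (-3.87).

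Of the 5 HSP90 genes, 4 rose and 1 did not pass (MpHSP90-5, log2 -0.40, adjusted p = 0.303), with the same counts adjusted over the list alone. MpHSP90-5 stood at 1.85 ± 0.357 CPM without and 1.39 ± 0.0240 with heat, so its values rest on few reads. The list had a median log2 of 2.89 (adjusted p = 2.46e-04, and adjusted p = 0.214 with an estimated correlation). Of the 25 histone genes, 22 fell, 2 rose and 1 did not pass, also when adjusted over the list alone, with a median of -1.20 (adjusted p = 2.96e-06, and adjusted p = 0.261 with an estimated correlation). MpH4d fell by 3.01 (adjusted p = 5.91e-10) and MpH1, the linker histone, by 1.28, while MpH2B.1 rose by 1.11. Of 17 cell cycle genes 12 fell and 5 did not pass, again with the same counts adjusted over the list alone (median -1.08, adjusted p = 0.0339, and adjusted p = 0.491 with an estimated correlation). Among them were MpMCM4 (-1.75) and MpMCM6 (-1.51), of the helicase that opens replication origins, and MpCDKB (-1.11), a mitotic kinase. Of 25 cell wall genes 13 fell, 4 rose and 8 did not pass, the same when adjusted over the list alone (median -0.68, adjusted p = 0.0418, and adjusted p = 0.261 with an estimated correlation). Expansins, which loosen walls, stood on each side, with MpExpansin14 at -2.15 and MpExpansin20 at 3.00. Of 49 peroxidase genes 17 fell, 2 rose and 30 did not pass, the same when adjusted over the list alone (median -0.37, adjusted p = 0.0232, and adjusted p = 0.261 with an estimated correlation), with MpPOD26 at -2.53.

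Of 57 genes of the phenylpropanoid list, enzymes on the way to flavonoids and other phenolics, 25 rose, 17 fell and 15 did not pass, or 26 and 18 adjusted over the list alone (median 0.18, adjusted p = 0.0418, and adjusted p = 0.261 with an estimated correlation). MpPAL7 (3.52) and Mp4CL1 (2.80, adjusted p = 3.62e-17) rose, and MpPAL1 (-2.68) and MpPKS/CHS2 (-1.95) fell. Among 6 genes of abscisic acid signalling 4 rose, 1 fell and 1 did not pass, the same when adjusted over the list alone (median 0.41, adjusted p = 0.0339, and adjusted p = 0.261 with an estimated correlation), and the receptor gene MpPYL1 rose by a log2 of 1.07. Of 49 antioxidant enzymes 14 rose, 7 fell and 28 did not pass, the same when adjusted over the list alone (median 0.03, adjusted p = 0.287). Of 40 genes of LEA proteins, which protect dry cells, 9 rose, 13 fell and 18 did not pass, or 9 and 14 adjusted over the list alone (median -0.07, adjusted p = 0.287). MpAPX3 (2.04), an ascorbate peroxidase, MpGST9 (2.81), a glutathione transferase, and the dehydrin gene MpDHN2 (1.58) rose, and MpDHN3 fell by 1.71. Of 4 reproductive regulators, the sperm regulator MpDUO1 rose by 2.19 and MpMID by 0.43 while MpRKD (-0.83) and MpR2R3-MYB1 (-2.46) fell (adjusted p = 0.571 for the list). The level of MpDUO1 was low in BC3 controls (0.515 ± 0.0272 CPM, 23 reads), so its rise in Tak-1 may also rest on few reads. Of 3 chlorophyll genes, too few to test as a list, MpCHLD fell by 0.28 (adjusted p = 0.0147), and MpGUN5 stood at -0.16 and MpCHLI1/2-like at 0.09. In all, 3442 genes were higher and 3423 lower of 13432 tested (51.1%), of which 958 and 1119 changed at least 2-fold.

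In the female wild type BC3, MpHSP90-1, MpHSP90-4 and MpHSF1 also rose with heat. MpHSP90-1 rose from 390.2 ± 4.87 to 4659.8 ± 70.4 CPM (log2 3.58 ± 0.07, adjusted p = 2.36e-22), MpHSP90-4 by a log2 of 3.31 and MpHSF1 by 1.199 ± 0.13 (adjusted p = 3.02e-08). MpNBS-LRR17 (4.93), MpLDAP (3.88), MpBBX6 (3.42), Mp4CL1 (3.06) and MpGST9 (2.88) were again among the largest rises, and MpBHLH4 (-4.58), MpERF7 (-3.92) and MpBHLH2 (-2.88) among the largest falls, with the receptor kinase gene MpRLK-Pelle_RKF3c at -4.71. Of 5 HSP90 genes 4 rose and 1 did not pass, the same when adjusted over the list alone (median 2.52, adjusted p = 1.35e-04, and adjusted p = 0.178 with an estimated correlation). Of 25 histone genes 19 fell, 2 rose and 4 did not pass, the same when adjusted over the list alone (median -0.92, adjusted p = 1.35e-04, and adjusted p = 0.435 with an estimated correlation). Of 17 cell cycle genes 12 fell, or 13 adjusted over the list alone, and 5 did not pass over all genes (median -0.91). Of 49 peroxidases 15 fell, 3 rose and 31 did not pass, the same adjusted over the list alone (median -0.41). Of 49 antioxidant enzymes 17 rose, 5 fell and 27 did not pass, the same adjusted over the list alone (median 0.12). Each of these lists had an adjusted p = 0.0242, and an adjusted p = 0.435 with an estimated correlation. The cell wall (adjusted p = 0.110), phenylpropanoid (adjusted p = 0.327), abscisic acid (adjusted p = 0.124) and LEA lists (adjusted p = 0.669) did not pass. In total 3205 genes were higher and 3218 lower, of which 909 and 826 changed at least 2-fold. The wild types share no library, and 2445 genes were higher and 2396 lower with heat in both, against 821 and 820 if the comparisons were independent. Of the 909 genes that rose at least 2-fold in BC3, 764 rose and 4 fell in Tak-1 (785 and 5 adjusted over the list alone), with a median log2 of 1.47 (adjusted p = 6.91e-63, and adjusted p = 9.35e-09 with an estimated correlation).

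**Figure D1:**
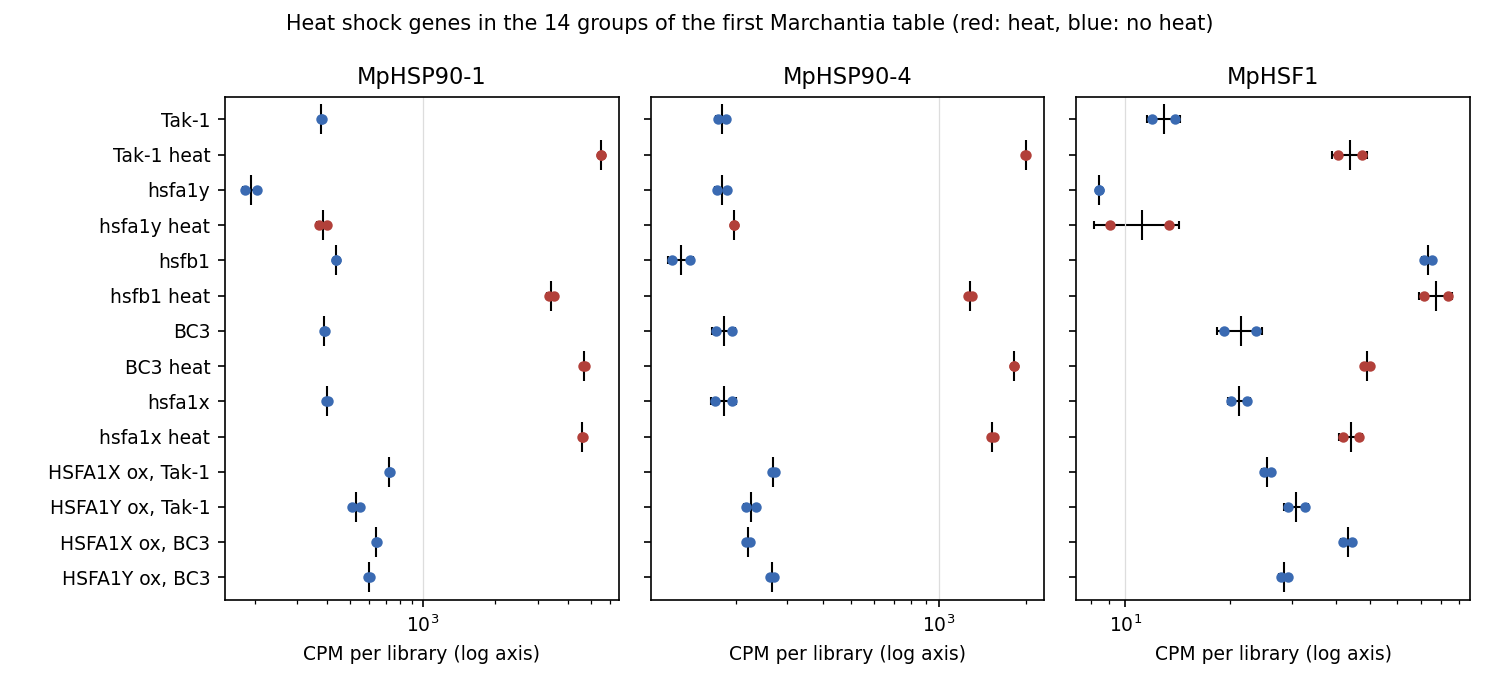
Levels of MpHSP90-1, MpHSP90-4 and MpHSF1 in CPM on a log axis for the 14 groups of the first experiment, with a point for each library, a black tick for the mean, a bar for the SD, heat in red and no heat in blue. MpHSP90-1 stood at 5482 CPM in heated Tak-1 and at 384 in heated hsfa1y, and MpHSF1 at 73.5 in hsfb1 without heat.

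Whether the heat response differs in the hsfa1y knockout was read from its heat and control libraries and from the interaction with Tak-1. In hsfa1y MpHSP90-1 rose from 194 ± 15.1 to 384 ± 19.8 CPM (log2 0.99 ± 0.06, adjusted p = 8.81e-12), which is lower than its rise in Tak-1 by a log2 of -2.87 ± 0.09 (adjusted p = 3.01e-17). MpHSP90-4 stood at 179.6 ± 9.68 CPM without and 197 ± 0.727 with heat (log2 0.13, adjusted p = 0.172), with an interaction of -3.34 ± 0.11 (adjusted p = 7.10e-17). MpHSP90-2 (Mp2g04900) kept a rise of 1.73, with an interaction of -1.16, and MpHSF1 one of 0.42 ± 0.15 (adjusted p = 0.0302), with an interaction of -1.35 ± 0.21. MpHSF1 stood at 8.41 and 8.44 CPM in the hsfa1y controls and at 9.02 and 13.3 with heat, so its rise rests mainly on heat replicate 2. The rises of MpNBS-LRR17 (interaction -4.94), MpExpansin20 (-3.38), MpLDAP (-2.98 ± 0.12, adjusted p = 2.09e-15) and Mp4CL1 (-2.85) were also smaller. Other genes kept or gained a rise. MpPKS/CHS13 went from 8.42 ± 1.42 to 248 ± 28.3 CPM (log2 4.88), and MpPAL6 (4.63), MpPAL7 (4.61) and MpGCAM1 (Mp6g04830, 4.69), a regulator of gemma cup formation, rose too. MpERF21 (-6.30), MpBHLH2 (-4.16) and MpCTR1 (Mp8g15840, -2.80), a kinase of ethylene signalling, fell in heated hsfa1y. The auxin synthesis gene MpYUC2 had a heat response higher than in Tak-1 by a log2 of 2.39.

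Within the heated and control hsfa1y libraries, 2 of the 5 HSP90 genes rose and 3 did not pass, the same adjusted over the list alone (median 0.68, adjusted p = 0.0102, and adjusted p = 0.251 with an estimated correlation). That median is the value of MpHSP90-5, which did not pass and stood at 1.51 ± 0.555 CPM without and 2.43 ± 0.122 with heat. Phenylpropanoid genes rose in 22 and fell in 10 cases with 25 not passing, or 23 and 10 adjusted over the list alone (median 0.09, mean 0.71, adjusted p = 0.0102, and adjusted p = 0.251 with an estimated correlation), with MpDFR-like12 at 1.66 and MpC4H1 at 1.26. Of 6 abscisic acid genes 3 rose and 3 did not pass, the same adjusted over the list alone (median 0.48, adjusted p = 0.0130, and adjusted p = 0.251 with an estimated correlation), and MpABI5B rose by 1.21. Histone genes fell in 13 and rose in 2 cases with 10 not passing, the same adjusted over the list alone (median -0.64, adjusted p = 0.0102, and adjusted p = 0.817 with an estimated correlation). The median of the peroxidase list was 0.15 while its test pointed down (11 rose, 14 fell and 24 did not pass, or 14 and 14 adjusted over the list alone, adjusted p = 0.624), and the cell wall list had a median of -0.12 and a mean of 0.08 (adjusted p = 0.979). Of the 909 genes that rose at least 2-fold in BC3, 482 rose and 65 fell in hsfa1y, or 497 and 71 adjusted over the list alone (median 0.62, adjusted p = 4.14e-18, and adjusted p = 2.39e-05 with an estimated correlation). In total 2969 genes were higher and 3008 lower, and 2121 of the higher and 2198 of the lower genes moved the same way in Tak-1, against 761 and 767 if independent.

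The interaction showed 886 genes with a higher and 1059 with a lower heat response in hsfa1y than in Tak-1. Of the 909 genes induced at least 2-fold in BC3, 421 had a lower and 29 a higher response in hsfa1y, or 465 and 39 adjusted over the list alone (median -0.78, adjusted p = 8.32e-45, and adjusted p = 1.73e-07 with an estimated correlation). Of the 826 lowered genes 252 had a higher and 8 a lower response, or 302 and 12 adjusted over the list alone (median 0.60, adjusted p = 7.76e-20, and adjusted p = 1.04e-06 with an estimated correlation). Of the HSP90 genes 4 had a lower response and 1 did not pass, and 4 were lower and 1 higher adjusted over the list alone (median -1.16, adjusted p = 8.87e-06, and adjusted p = 0.0730 with an estimated correlation). The gene that was higher was MpHSP90-5 (1.08), of the low level given above. Responses were higher for 10 of 25 histone genes, or 13 adjusted over the list alone, with 15 not passing over all genes (median 0.56, adjusted p = 2.15e-05, and adjusted p = 0.335 with an estimated correlation), as for MpH2B.4 at 1.29. LEA genes (12 of 40 higher and 28 not passing, the same adjusted over the list alone, adjusted p = 0.00384, and adjusted p = 0.132 with an estimated correlation) included MpDHN3 at 0.90. Peroxidases (10 of 49 higher and 39 not passing, or 13 higher and 2 lower adjusted over the list alone, adjusted p = 0.00995, and adjusted p = 0.243 with an estimated correlation) included MpPOD143 at 1.88. Of the cell wall genes 5 were higher, 3 lower and 17 not passing, the same adjusted over the list alone (median 0.56, adjusted p = 0.00604, and adjusted p = 0.132 with an estimated correlation). Of the phenylpropanoid genes 15 were higher, 5 lower and 37 not passing, or 19 and 6 adjusted over the list alone (adjusted p = 0.0356, and adjusted p = 0.261 with an estimated correlation).

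Without heat, named genes were higher and lower in hsfa1y than in Tak-1. MpPR1o (Mp5g16820), of the PR1 family of secreted proteins induced by pathogens, stood at 48.1 ± 0.915 CPM in hsfa1y and at 1.42 ± 0.105 in Tak-1 (log2 5.07), and MpMLS3 was higher by 6.02. MpGST26 (-4.39) and Mp4CL1 (-1.16, adjusted p = 2.40e-07) were lower, as were MpHSP90-1 (-0.96, adjusted p = 3.52e-10) and MpHSF1 (-0.62, adjusted p = 0.0118). Phenylpropanoid genes were higher in 14 and lower in 3 of 57 cases with 40 not passing, or 21 and 4 adjusted over the list alone (median 0.21, adjusted p = 0.00388, and adjusted p = 0.181 with an estimated correlation), with MpPKS/CHS18 at 1.71 and MpPKS/CHS16 at 1.01. Of 5 HSP90 genes 1 was lower and 4 did not pass, the same adjusted over the list alone (median -0.14, adjusted p = 0.0107, and adjusted p = 0.300 with an estimated correlation). Of 25 cell wall genes 3 were lower, among them MpExpansin32 (-0.95), and 22 did not pass, the same adjusted over the list alone (adjusted p = 0.0107, and adjusted p = 0.181 with an estimated correlation). The histone list passed at the preset correlation alone (median -0.25, adjusted p = 0.00388, and adjusted p = 0.702 with an estimated correlation). Of its 25 members edgeR called 0, also adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 1 called by DESeq2. The heat-induced genes of BC3 were lower in 125 and higher in 33 of 909 cases, or 155 and 45 adjusted over the list alone (median -0.11, adjusted p = 7.56e-06, and adjusted p = 0.0107 with an estimated correlation). In total 653 genes were higher and 423 lower, a count of 1076 that moved to 463 without Tak-1 control 1, 496 without Tak-1 control 2 and 401 without hsfa1y control 1.

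In hsfa1x, compared within the female background, MpHSP90 genes and MpHSF1 rose with heat. MpHSP90-1 rose from 399 ± 6.50 to 4595 ± 50.7 CPM (log2 3.53 ± 0.07, adjusted p = 3.93e-22), MpHSP90-4 by 3.07, MpHSP90-2 by 2.63 and MpHSF1 by 1.07 (adjusted p = 3.02e-07). The interactions with BC3 were -0.05 for MpHSP90-1 (adjusted p = 0.804), -0.24 for MpHSP90-4 (adjusted p = 0.202) and -0.13 for MpHSF1 (adjusted p = 0.744). MpNBS-LRR17 (3.56), MpBBX6 (3.34) and MpLDAP (3.03) rose too, and MpPR9d (-5.18), MpBHLH4 (-5.04) and MpIAMT1 (-3.32), a methyltransferase of auxin, fell. Of 5 HSP90 genes 4 rose and 1 did not pass, or 4 rose and 1 fell adjusted over the list alone (median 2.63, adjusted p = 1.63e-04, and adjusted p = 0.157 with an estimated correlation). Of 25 histone genes 12 fell, 2 rose and 11 did not pass, or 13 and 2 adjusted over the list alone (median -0.52, adjusted p = 0.0155, and adjusted p = 0.901 with an estimated correlation). For the 17 cell cycle genes edgeR called 0, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2 (median -0.18, list adjusted p = 0.963). In total 2657 genes were higher and 2956 lower, with 2136 and 2181 of them moving the same way in BC3, against 634 and 708 if independent.

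The heat response of MpERF18, a transcription factor gene of the ERF family, differed between hsfa1x and BC3. It stood at 33.4 ± 0.122 CPM without and 107 ± 0.678 CPM with heat in BC3 and at 115 ± 9.72 and 121 ± 0.649 CPM in hsfa1x, an interaction of -1.61 (adjusted p = 1.82e-09). MpERF21 (2.88, adjusted p = 0.00102), MpSAUR14 (2.55), MpLEA-like59 (2.08) and the calmodulin-like MpCML42 (1.88) had a higher response. Without heat these genes were lower in hsfa1x than in BC3 (-3.36, -1.78, -1.94 and -1.71 in the same order). The interaction uses the same control libraries, so these higher responses can reflect the lower control levels. Of the 958 genes induced at least 2-fold in Tak-1, 124 had a lower and 5 a higher response in hsfa1x, or 167 and 8 adjusted over the list alone (median -0.23, adjusted p = 9.52e-08, and adjusted p = 0.00679 with an estimated correlation). Of the 1119 lowered genes 97 had a higher and 43 a lower response, or 137 and 61 adjusted over the list alone (median 0.19, adjusted p = 4.38e-06, and adjusted p = 0.00224 with an estimated correlation). Antioxidant genes had a lower response in 3 of 49 cases with 46 not passing, the same adjusted over the list alone (median -0.15, adjusted p = 0.00540, and adjusted p = 0.710 with an estimated correlation), with MpGST9 at -0.86. Of the cell wall genes 1 had a higher response and 24 did not pass, or 4 adjusted over the list alone (median 0.27, adjusted p = 0.00102, and adjusted p = 0.0994 with an estimated correlation). Among histone genes 1 was higher, 1 lower and 23 did not pass, the same adjusted over the list alone (median 0.18, adjusted p = 0.00400, and adjusted p = 0.710 with an estimated correlation). The cell cycle list had a median of 0.64 (adjusted p = 2.39e-04, and adjusted p = 0.566 with an estimated correlation), while edgeR called 0 of its 17 members, also adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 0 called by DESeq2. In total 231 genes had a higher and 557 a lower response, a count of 788 that was 91 in a fit to only the groups compared. Without the filter on low counts 555 had a higher and 560 a lower response. It moved to 319 without BC3 control 1, 510 without BC3 heat 2, 333 without hsfa1x control 1, 1587 without hsfa1x control 2 and 337 without hsfa1x heat 2.

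Without heat, the cell wall list was lower in hsfa1x than in BC3. Of 25 cell wall genes 12 were lower, 1 higher and 12 did not pass, or 19 lower and 1 higher adjusted over the list alone (median -0.55, adjusted p = 1.31e-06). This list also passed with an estimated correlation (adjusted p = 0.00832 with an estimated correlation), the 1 call of 150 list tests to do so. MpExpansin32 (-0.92, adjusted p = 4.63e-08), the cellulose synthase-like MpCSLD7 (-0.69) and MpExpansin15 (-0.63) were lower and MpExpansin20 was higher (0.83). Phenylpropanoid genes were higher in 16 and lower in 5 cases with 36 not passing, or 17 and 5 adjusted over the list alone (median 0.15, adjusted p = 0.0284, and adjusted p = 0.437 with an estimated correlation), with MpPKS/CHS16 at 376 ± 57.8 CPM against 146 ± 6.40 (log2 1.36). Antioxidant genes were higher in 11 cases with 38 not passing, the same adjusted over the list alone (median 0.09, adjusted p = 0.0360, and adjusted p = 0.790 with an estimated correlation), with MpGST9 at 0.76. Of the cell cycle genes 1 was lower and 16 did not pass, the same adjusted over the list alone (median -0.50, adjusted p = 0.0284, and adjusted p = 0.790 with an estimated correlation). MpMLS5 was higher (2.63) and MpERF21 lower (-3.36, adjusted p = 5.40e-08), and MpHSP90-1 (0.03, adjusted p = 0.792) and MpHSF1 (-0.02, adjusted p = 0.956) did not pass. With no library in common, hsfa1x against BC3 and hsfa1y against Tak-1 had 445 higher and 161 lower genes in both, against 73.9 and 31.1 if independent. Differences between replicates correlated between the hsfa1x and hsfa1y controls (r = 0.241, the highest of 91 pairs of groups). These comparisons may therefore share variation between libraries, which the values for independence leave out. In total 1520 genes were higher and 988 lower, a count of 2508 that was 1238 in a fit to only the groups compared, 1668 without BC3 control 1 and 1409 without hsfa1x control 1.

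In hsfb1, compared within the male background, heat raised HSP90 genes while MpHSF1 was already high. MpHSP90-1 rose from 435 ± 0.0623 to 3409.6 ± 118 CPM (log2 2.97 ± 0.07, adjusted p = 7.10e-21), MpHSP90-4 from 129.7 ± 12.6 to 1281 ± 28.5 CPM (3.30) and MpHSP90-2 by 2.49. MpHSF1 stood at 0.08 ± 0.12 (adjusted p = 0.638). The interactions with Tak-1 were -1.69 ± 0.18 for MpHSF1 (adjusted p = 5.82e-07), -0.89 ± 0.09 for MpHSP90-1 (adjusted p = 2.52e-07), -0.39 for MpHSP90-2 (adjusted p = 0.0224) and -0.17 for MpHSP90-4 (adjusted p = 0.36). MpNBS-LRR17 (4.97), MpLDAP (3.29) and MpBBX6 (3.24) rose, and MpBHLH4 (-4.29), the chitinase family gene MpGH19.7 (-3.39) and MpCTR1 (-3.38) fell. Of 5 HSP90 genes 4 rose and 1 did not pass, the same adjusted over the list alone (median 2.49, adjusted p = 4.87e-05, and adjusted p = 0.113 with an estimated correlation). Of 25 histone genes 16 fell, 2 rose and 7 did not pass, the same adjusted over the list alone (median -0.68, adjusted p = 0.00163, and adjusted p = 0.554 with an estimated correlation). Of 49 peroxidases 17 fell, 1 rose and 31 did not pass, the same adjusted over the list alone (median -0.52, adjusted p = 0.0246, and adjusted p = 0.373 with an estimated correlation). In total 2527 genes were higher and 2899 lower, and 2031 and 2107 of them moved the same way in Tak-1, against 648 and 739 if independent.

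Several genes of phenolic enzymes had a lower heat response in hsfb1 than in Tak-1. Of 57 phenylpropanoid genes 19 had a lower response, 1 a higher one and 37 did not pass, or 22 and 1 adjusted over the list alone (median -0.18, adjusted p = 1.14e-04, and adjusted p = 0.0815 with an estimated correlation). MpPKS/CHS13 (-2.51), MpPAL6 (-2.37), MpPKS/CHS14 (-1.69), MpDFR-like12 (-1.05) and MpC4H1 (-0.98) were lower, and MpPKS/CHS2 was higher (1.08). LEA genes had a higher response in 5 of 40 cases with 35 not passing, the same adjusted over the list alone (median 0.34, adjusted p = 3.07e-04, and adjusted p = 0.0815 with an estimated correlation), with MpDHN3 at 2.45. Of the histone genes 2 had a higher response and 23 did not pass, or 11 adjusted over the list alone (median 0.68, adjusted p = 1.50e-04, and adjusted p = 0.501 with an estimated correlation). Of the HSP90 genes 2 had a lower response and 3 did not pass, the same adjusted over the list alone (median -0.17, adjusted p = 0.0342, and adjusted p = 0.461 with an estimated correlation). MpERF7 (3.02), MpPPO3 (3.00) and MpSAUR14 (2.78) had a higher response. Of the 909 genes induced at least 2-fold in BC3, 163 had a lower and 48 a higher response in hsfb1 than in Tak-1, or 188 and 58 adjusted over the list alone (median -0.17, adjusted p = 6.88e-04, and adjusted p = 0.0300 with an estimated correlation). Of the 826 lowered genes 164 had a higher and 30 a lower response, or 197 and 34 adjusted over the list alone (median 0.37, adjusted p = 3.21e-12, and adjusted p = 3.64e-05 with an estimated correlation). In total 706 genes had a higher and 883 a lower response, a count of 1589 that was 1055 without Tak-1 control 2 and 1048 without hsfb1 control 1.

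Without heat, MpHSF1 was higher in hsfb1 than in Tak-1 by a log2 of 2.50 ± 0.13 (adjusted p = 2.09e-12). The wall-associated kinase gene MpRLK-Pelle_WAK2 (4.04), the water channel gene MpTIP2 (3.19), MpPOD88 (3.03) and MpPR1o (2.97) were also higher. The wax synthesis gene MpCER3a (-6.38, adjusted p = 7.34e-09) and the transporter gene MpABCG3 (-4.85) were lower. Of 25 cell wall genes 12 were higher, 1 lower and 12 did not pass, the same adjusted over the list alone (median 0.55, adjusted p = 0.00293, and adjusted p = 0.154 with an estimated correlation), with MpExpansin6 at 1.26 and MpExpansin32 at 1.25. Of 25 histone genes 15 were lower and 10 did not pass, or 18 lower adjusted over the list alone (median -0.40, adjusted p = 8.79e-05, and adjusted p = 0.797 with an estimated correlation), with MpH3.3a at -0.87. The heat-induced genes of BC3 were split, with 148 higher and 151 lower, or 146 and 150 adjusted over the list alone (adjusted p = 0.773). In total 2390 genes were higher and 2222 lower. The library numbers in the labels run in one block for hsfb1 (S25 to S28), apart from the Tak-1 libraries it is compared with.

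The overexpression lines were compared with the wild type of their background without heat, to see which genes differ in plants labelled as overexpressing HSFA1. The labels number all 8 overexpression libraries in one block (S1 to S8), apart from the wild-type libraries, so differences from the wild type, and overlaps between these lines, coincide with that block. In HSFA1X plants of the Tak-1 background, MpHSP90-1 stood at 725 ± 3.28 CPM against 378 ± 2.41 (log2 0.94, adjusted p = 4.80e-11), MpHSP90-4 was higher by 0.59 and MpHSF1 by 0.98 (adjusted p = 5.59e-06). The terpene synthase-like MpMTPSL-like (5.20), the dirigent gene MpDIR28 (2.59), Mp4CL1 (2.50) and MpGST26 (2.46) were higher, and MpWRKY14 (-3.74) and MpERF21 (-3.52) lower. Of 5 HSP90 genes 3 were higher and 2 did not pass, the same adjusted over the list alone (median 0.42, adjusted p = 0.0290, and adjusted p = 0.609 with an estimated correlation). Antioxidant genes were higher in 17 and lower in 6 of 49 cases with 26 not passing, or 18 and 6 adjusted over the list alone (median 0.12, adjusted p = 0.0406, and adjusted p = 0.609 with an estimated correlation). Among 17 cell cycle genes 4 were higher and 13 did not pass, the same adjusted over the list alone (median 0.50, adjusted p = 0.0290, and adjusted p = 0.609 with an estimated correlation). MpCYCD_1 was higher by 0.93. Of the 909 heat-induced genes of BC3, 350 were higher and 90 lower, or 368 and 103 adjusted over the list alone (median 0.24, adjusted p = 1.17e-09, and adjusted p = 7.36e-04 with an estimated correlation). Of the 826 lowered genes 302 were lower and 79 higher, or 311 and 89 adjusted over the list alone (median -0.27, adjusted p = 1.67e-06, and adjusted p = 7.36e-04 with an estimated correlation). In total 2034 genes were higher and 2334 lower.

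In HSFA1Y plants of the Tak-1 background, MpHSF1 was higher by 1.25 (adjusted p = 9.95e-08) and MpHSP90-1 by 0.48 (adjusted p = 1.25e-06), at 529 ± 26.1 CPM. MpMTPSL-like (4.55), MpExpansin6 (2.48, adjusted p = 7.04e-15) and the cytokinin oxidase gene MpCKX1 (2.23) were higher, and MpERF21 (-5.87), MpGH19.3 (-4.37) and MpPR6c (-3.76) were lower. Of 25 cell wall genes 13 were higher, 3 lower and 9 did not pass, or 14 and 3 adjusted over the list alone (median 0.85, adjusted p = 0.00432, and adjusted p = 0.135 with an estimated correlation). The heat-induced genes of BC3 were higher in 258 and lower in 168 cases, or 265 and 177 adjusted over the list alone (median 0.10, adjusted p = 0.0121, and adjusted p = 0.0960 with an estimated correlation), and the lowered genes lower in 316 and higher in 98, or 326 and 107 adjusted over the list alone (median -0.25, adjusted p = 5.46e-05, and adjusted p = 0.00419 with an estimated correlation). Of the 322 genes induced in BC3 by a log2 of at least 2, 122 were higher and 41 lower (median 0.34, adjusted p = 1.51e-06, and adjusted p = 0.00286 with an estimated correlation). The wider induced set did not pass with an estimated correlation, so this result depends on the bound. At the bound of 2, HSFA1X plants of the Tak-1 background had 151 of these genes higher and 23 lower (median 0.58). In total 2162 genes were higher and 2624 lower.

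In the female background, MpHSP90-1 was higher by 0.71 in HSFA1X plants (adjusted p = 7.89e-09) and by 0.62 in HSFA1Y plants (adjusted p = 1.03e-07), and MpHSF1 by 1.01 (adjusted p = 2.08e-06) and 0.41 (adjusted p = 0.0245). Mp4CL1 was higher in both (2.17 and 1.89), and MpBHLH4 (-4.96 and -4.58), MpERF21 (-4.51 and -3.81) and the terpene synthase gene MpTPS6 (-4.68 and -3.36) were lower in both. In each, 2 of the 5 HSP90 genes were higher (list adjusted p = 0.271 for HSFA1X and adjusted p = 0.179 for HSFA1Y). Of the 958 genes induced at least 2-fold in Tak-1, 282 were higher and 59 lower in HSFA1X plants, or 307 and 66 adjusted over the list alone (median 0.18, adjusted p = 2.34e-10, and adjusted p = 0.00246 with an estimated correlation). In HSFA1Y plants 299 were higher and 60 lower, or 329 and 69 adjusted over the list alone (median 0.18, adjusted p = 3.43e-11, and adjusted p = 0.00157 with an estimated correlation). The HSFA1X lines of the female and male backgrounds shared 870 higher and 986 lower genes, against 213 and 258 if independent, and the HSFA1Y lines 683 and 982, against 199 and 287. In HSFA1X plants 1407 genes were higher and 1484 lower, a count of 2891 that was 1764 without HSFA1X overexpression control 2 and 1882 without BC3 control 1. In HSFA1Y plants 1235 were higher and 1470 lower, a count of 2705 that was 1771 without HSFA1Y overexpression control 2.

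**Figure D2:**
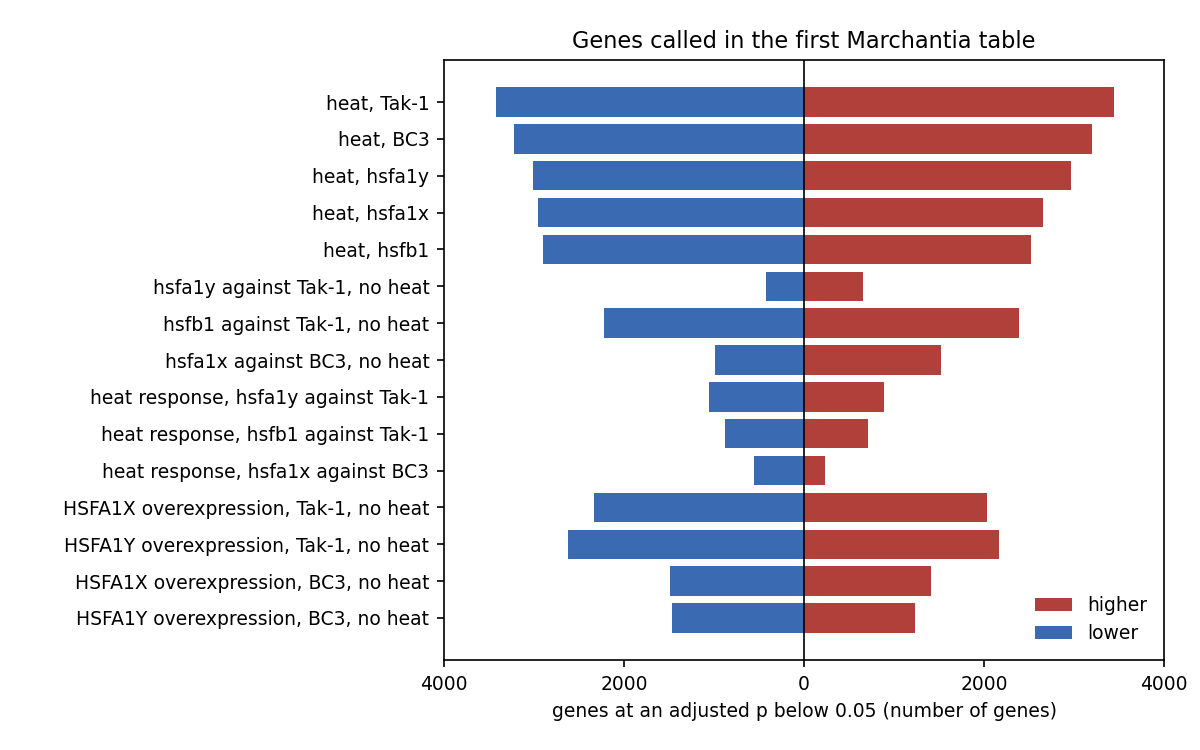
Number of genes at an adjusted p below 0.05 (x axis) in each of the 15 comparisons of the first experiment, with bars for genes that were higher (red) and lower (blue). Heat in Tak-1 gave 3442 higher and 3423 lower genes, and the interaction of hsfa1x with BC3 gave 231 and 557.

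The time course of heat was read from the second experiment, first in BC3, whose libraries each held 4 of 5 Tak-1 and 13 or 14 of 16 Tak-2 marker transcripts. Its identifiers have no symbols in the reference used here, so genes are given by identifier. After 1 h, Mapoly0010s0142.1 stood at 2464 ± 36.9 CPM against 0.0240 in control libraries and Mapoly0010s0141.1 at 1622 ± 45.8 against 0.0240, levels that rest on 1 control read each. Mapoly0214s0010.1 fell from 59.4 ± 4.62 to 3.90 ± 0.739 CPM (log2 -3.94 ± 0.14, adjusted p = 1.52e-12) and Mapoly0221s0006.1 fell as well (-3.85). After 5 h, Mapoly0076s0003.1 stood at 14676 ± 186 CPM against 0.101 (4 control reads) and Mapoly0214s0010.1 fell further to 0.357 CPM (log2 -7.39 ± 0.21, adjusted p = 6.95e-14). Between 1 and 5 h, Mapoly0018s0027.1 rose from 0.2501 to 24.3 CPM (6.60 ± 0.33, adjusted p = 1.10e-09) and Mapoly0130s0026.1 fell (-4.60). At 1 h 2818 genes were higher and 2757 lower, at 5 h 3786 and 3582, and between these times 2734 rose and 2686 fell. At least 2-fold changes numbered 1068 and 664 at 1 h and 1652 and 1479 at 5 h.

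For Tak-1 and Tak-2 some control libraries did not carry the transcripts of their label. V-linked gene models, which are male, summed to 417 CPM in the library labelled Tak-1 control 1, 1.34 in Tak-1 control 2, 1029 in Tak-2 control 1 and 1.09 in Tak-2 control 2, while heated Tak-1 libraries had 434 to 800 CPM and heated Tak-2 and BC3 libraries 0.384 to 1.14. Of 16 transcripts outside this set that were found in heated Tak-2 and not in heated Tak-1 libraries, the library labelled Tak-1 control 2 held 16, Tak-1 control 1 held 15 and Tak-2 control 1 held 0. Mapoly0018s0008.1 had 0 reads in heated Tak-1 libraries at 1 h and 173 ± 56.9 CPM in libraries labelled Tak-1 control, at least 976-fold more, but also 97.4 ± 138 CPM in those labelled Tak-2 control. Libraries were kept in the groups of their labels, so comparisons that use these control libraries mix heat with accession.

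With this limit, heat genes of BC3 also stood high in Tak-1 and Tak-2. Mapoly0010s0142.1 stood at 2394 ± 61.0 CPM against 0.310 in Tak-1 and at 2335 ± 64.4 against 0.0778 (3 control reads) in Tak-2 after 1 h. Mapoly0076s0003.1 reached 9745 ± 262 and 15951 ± 366 CPM after 5 h. In Tak-1 3241 genes were higher and 3183 lower at 1 h and 3935 and 3781 at 5 h, with 2915 rising and 2918 falling between these times. In Tak-2 the counts were 3181 and 3188 at 1 h, 3923 and 3808 at 5 h, and 2870 and 3068 between them. Without the library labelled Tak-1 control 2 and the one labelled Tak-2 control 1, the totals were 6190 at 1 h and 7567 at 5 h in Tak-1, from 6424 and 7716, and 6002 and 7430 in Tak-2, from 6369 and 7731. The Tak-1 control left carries markers of both accessions. BC3 and Tak-1 share no library, and 2236 genes were higher and 2005 lower at 1 h in both, against 843 and 810 if independent, and 3119 and 2856 at 5 h, against 1375 and 1250.

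The interaction of BC3 with Tak-1 called 1884 genes at 1 h (939 higher and 945 lower in BC3) and 2621 at 5 h (1362 and 1259). That of Tak-2 with Tak-1 called 2380 genes at 1 h (1189 and 1191) and 3829 at 5 h (1811 and 2018). In these counts, MapolyY_A0041.1 stood at 204 ± 0.503 CPM in heated Tak-1 at 1 h, at 0 reads in heated Tak-2 and at 94.6 ± 134 CPM in libraries labelled Tak-2 control. Without the pair of doubted libraries the counts were 2305 and 2894 for BC3 and 1605 and 3033 for Tak-2. The lone Tak-1 control left in them carries 4 of 5 Tak-1 and 15 of 16 Tak-2 markers, so these counts also mix heat with accession. The count of 1884 moved to 1217 without the library labelled Tak-1 control 2, to 1161 and 1171 without Tak-1 1 h heat 1 and 2, and to 1082 and 1185 without BC3 1 h heat 1 and 2. That of 2621 moved to 1739 without Tak-1 5 h heat 2. The count of 2380 was 1178 in a fit to only the groups compared, 1371 without the library labelled Tak-1 control 2, 1491 without Tak-1 1 h heat 2 and 1364 without Tak-2 1 h heat 2.

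**Figure D3:**
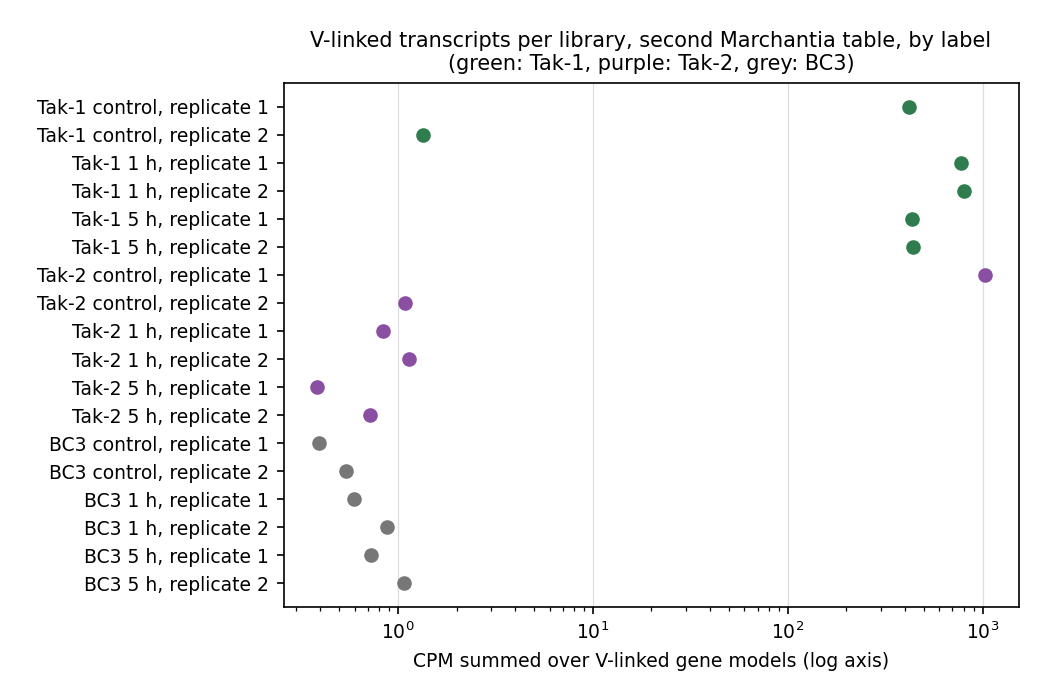
Reads of V-linked gene models as CPM summed per library on a log axis for the 18 libraries of the second experiment by label, with a point for each library, Tak-1 in green, Tak-2 in purple and BC3 in grey. The library labelled Tak-1 control 2 stood at 1.34 CPM and the one labelled Tak-2 control 1 at 1029.

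In *K. nitens*, an alga related to the ancestors of land plants, 2 h of heat changed most genes, and more genes fell than rose by at least 2-fold. The gene KFL_005170100 stood at 125 ± 4.38 CPM with heat (SD, n = 3) and had 0 reads in control libraries, so it was at least 952-fold higher, and KFL_000910330 stood at 7.70 ± 2.69 CPM against 0 reads (at least 58.7-fold). KFL_000180310 fell from 243 ± 52.5 to 0.167 CPM (log2 -10.42 ± 0.33, adjusted p = 1.03e-08), and KFL_001510040 stood at 12.3 ± 1.22 CPM without heat and had 0 reads with heat, at least 103-fold lower. No symbols were paired with these identifiers in the reference used here. Of 11387 genes tested, 4727 were higher and 4570 lower with heat. At least 2-fold changes numbered 1095 up and 2523 down, and at least 8-fold changes 121 up and 789 down. With DESeq2 size factors 4526 of all genes tested were higher and 4711 lower, so which direction held more called genes depends on the scaling. Of the 10 ways to split the 6 libraries into groups of 3, the labels gave 9297 genes by edgeR, and the other 9 gave 0 each, with 2 to 23 genes at an unadjusted p under 0.05 against 9415 for the labels. Each of the other 9 puts heated and control libraries in the same group. This widens the spread within groups, so few calls were likely from the start.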

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

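The interaction tests and the splits of the *K. nitens* libraries were fixed before the data were examined, and every use of a value to weigh an explanation for the other patterns was chosen only after the pattern had been seen.

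The results listed here are a difference between groups in heat response that passed the interaction test. In the first experiment these are the counts of genes with another heat response than the wild type, 1945 in hsfa1y, 1589 in hsfb1 and 788 in hsfa1x. In the second they are 2380 at 1 h and 3829 at 5 h for Tak-2 against Tak-1, and 1884 at 1 h and 2621 at 5 h for BC3 against Tak-1. These 4 counts use control libraries that carry transcripts of the other accession, so passing the test does not show that heat acted differently. Among the heat shock genes, hsfa1y differed from Tak-1 for MpHSF1 (-1.35), MpHSP90-1 (-2.87), MpHSP90-2 (-1.16), MpHSP90-3 (-0.59) and MpHSP90-4 (-3.34). In hsfb1 the differences were -1.69 for MpHSF1, -0.89 for MpHSP90-1 and -0.39 for MpHSP90-2.

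The first pattern is a set of control libraries in the second experiment whose transcripts differ from their labels. The library labelled Tak-1 control 2 detected 100% of 16 Tak-2 marker transcripts and 0 of 5 Tak-1 markers, and the library labelled Tak-2 control 1 detected 0 and 5, which is consistent with an exchange of these libraries. The library labelled Tak-1 control 1 held both sets, with median levels of 0.450 for Tak-1 and 0.651 for Tak-2 markers that sum to 1.101, which may reflect a mixture of RNA or tissue of both accessions. BC3 control libraries also carry 4 Tak-1 and 13 Tak-2 markers but at most 0.542 CPM of V-linked transcripts, against 417 CPM in this library (a median level of 0.417 over 13 V-linked genes), so a BC3 library alone would not give it. It stays open at which step this arose, and therefore how far the 4 interaction counts of that experiment reflect accession.

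The next pattern is the weaker heat induction in hsfa1y than in Tak-1. Suppose that part of the hsfa1y tissue had not been heated and nothing else differed. Genes that rose at least 2-fold in BC3 and also rose in Tak-1 could then rise less but would not fall. Of 764 such genes 48 (6.28%) fell in hsfa1y, against 1 in hsfb1. This argues against a mixed sample, part of it not heated, as the only cause. Unheated tissue together with a genotype effect could also give these falls, so a mixed sample beside another cause stays open. Under a weaker heat dose in the hsfa1y libraries, induced and lowered genes might keep a like share of their change. The median kept share, taken from differences in CPM, was 0.217 for induced and 0.775 for lowered genes, a gap of 0.557, against 0.0111 in hsfb1. A fall in CPM cannot exceed the control level while a rise has no such limit, so part of this gap can come from the scale. As log2 changes, the median over the 909 genes induced in BC3 was 0.62 in hsfa1y and 1.47 in Tak-1. Over the 826 lowered genes it was -0.97 and -1.57. A dose that acts on the 2 sets differently could also give this gap, so dose and genotype stay open.

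The last pattern is the higher MpHSF1 in hsfb1 without heat. A batch that shifts MpHSF1 alike with and without heat would not give the difference of -1.69 in its heat response, but that value reuses the control libraries that prompted the pattern. In the heat libraries MpHSF1 was also higher in hsfb1 (log2 0.82, adjusted p = 1.09e-05), and 84.0% (3872 of 4611) of the other genes that differ without heat kept their direction, which a batch and a genotype effect would each give. The rank of MpHSF1 among 1000 genes of like expression (the 100th percentile) restates the rise that prompted it, and does not bear on whether MpHSF1 is the gene disrupted in the hsfb1 line. Batch and genotype stay open for MpHSF1 and for these 4611 genes, because the labels number all hsfb1 libraries in one block.

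For *K. nitens*, 1 of the 10 splits of the libraries, the real one, gave as many called genes (9297), and 10 splits are too few to show a share under 0.05. The other splits also mix heated and control libraries within groups, so their low counts bear little on the question.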

How the results depend on the processing

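DESeq2 size factors, the DESeq2 test, no filter and the replicate block each kept 29 of 29 counts of called genes within 1.5 times, and a fit to only the groups compared kept 25 of 28. Which direction held more genes was less stable. With DESeq2 size factors it changed in *K. nitens*, in HSFA1Y plants of Tak-1 (2468 higher and 2419 lower) and in HSFA1X plants of BC3 (1513 and 1434), among others. With the replicate block 729 of 732 named values kept their direction and side of the threshold, with DESeq2 size factors 725 of 732, with the DESeq2 test 710 of 731, with no filter 704 of 732, in a fit to only the groups compared 647 of 724 (40 weaker and 37 stronger), without the pair of doubted control libraries 24 of 32 (8 weaker), and none reversed. Leaving out a library kept 122 of 146 counts within 1.5 times, and 3219 of 3512 named values. Such fits leave a group with a lone library, which is assumed to vary like the other groups. In a fit to only the groups compared, hsfa1x against BC3 without heat gave 1238 genes, its interaction 91, and the interaction of Tak-2 at 1 h 1178. Such fits have fewer samples to estimate the spread, but counts moved both ways. Tak-1 heat went from 6865 to 8142 and BC3 heat from 6423 to 4981. Counts varied more between libraries of the hsfa1x and BC3 groups (7.73 to 17.3 times counting error) than in Tak-1 controls (2.60) and heat (2.87). The fit to all groups shares its estimate of spread, so the 788 genes of the hsfa1x interaction may be too many. Without a library the ranges were 401 to 967 for hsfa1y without heat, 1409 to 2984 for hsfa1x without heat, 1048 to 1358 for the interaction of hsfb1, 319 to 1587 for that of hsfa1x, 1764 to 2537 for HSFA1X and 1771 to 2189 for HSFA1Y overexpression in BC3, 1364 to 3467 for the interaction of Tak-2 at 1 h, and 1082 to 1748 at 1 h and 1739 to 2445 at 5 h for that of BC3. For these the cause was not tested. Without a filter, 1115 genes passed in the interaction of hsfa1x, and the share with a higher response moved from 29.3% to 49.8%. The gene list tests with an estimated correlation in camera gave 1 call in place of 49 of 150, and the core sets 24 in place of 25 of 30. Core sets bound at a log2 of 2 in place of 1 gave 26 calls of 30, and also 26 with an estimated correlation. The planned core sets of 5 h in place of 1 h were not run, because identifiers differ between tables. With 2 libraries per group, depth limits genes of few reads most.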

Other observations

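The families and the hypothesis tested in this part were chosen only after the results were seen.

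Families of genes that share a symbol were tested beside the lists. Of 390 pairs of a family and a comparison, 20 passed at the preset correlation and 1 with an estimated correlation, and examples follow. Pathogenesis-related (PR) genes, which encode secreted defence proteins, were higher in hsfa1y than in Tak-1 in 10 of 24 cases with 14 not passing, or 14 higher and 1 lower adjusted over the list alone (median log2 1.17, adjusted p = 5.63e-07, and adjusted p = 0.0706 with an estimated correlation). In hsfa1x against BC3 they were higher in 11 cases, lower in 1 and not passing in 12, or 13 and 1 adjusted over the list alone (median 1.198, adjusted p = 9.20e-05, and adjusted p = 0.244 with an estimated correlation). In HSFA1X overexpression plants of BC3, 11 PR genes were lower and 13 did not pass, or 14 lower and 1 higher adjusted over the list alone (median -2.17, adjusted p = 6.60e-09, and adjusted p = 0.0279 with an estimated correlation). In HSFA1Y overexpression plants of BC3, 9 were lower, 1 was higher and 14 did not pass, the same adjusted over the list alone (median -1.12, adjusted p = 1.39e-06, and adjusted p = 0.0867 with an estimated correlation). Genes of the MAPKKK family, kinases at the top of signalling cascades, were lower in 14 of 23 cases with HSFA1X in Tak-1 with 9 not passing, or 16 adjusted over the list alone (median -0.39, adjusted p = 1.31e-04, and adjusted p = 0.831 with an estimated correlation).

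In hsfb1 without heat, glycoside hydrolase (GH) genes were higher in 37 and lower in 5 of 96 cases with 54 not passing, the same adjusted over the list alone (median 0.35, adjusted p = 2.08e-05, and adjusted p = 0.0536 with an estimated correlation). Dirigent (DIR) genes, which guide the coupling of phenolics, were higher in 15 and lower in 2 of 37 cases with 20 not passing, the same adjusted over the list alone (median 0.32, adjusted p = 0.0158, and adjusted p = 0.332 with an estimated correlation). TRIHELIX transcription factor genes were lower in 16 and higher in 1 of 35 cases with 18 not passing, the same adjusted over the list alone (median -0.19, adjusted p = 0.00163, and adjusted p = 0.117 with an estimated correlation). BHLH genes had a higher heat response in hsfa1y than in Tak-1 in 11 and a lower one in 3 of 38 cases with 24 not passing, or 14 and 3 adjusted over the list alone (median 0.29, adjusted p = 0.00237, and adjusted p = 0.168 with an estimated correlation).

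MpVg00470, a V-linked identifier without a symbol, stood at 44.0 ± 1.24 CPM in Tak-1 controls, 25.1 ± 2.54 in hsfa1y (log2 -0.80, adjusted p = 5.13e-06) and 308 ± 19.4 in HSFA1Y overexpression plants of the male background (log2 2.81, adjusted p = 7.71e-15). In HSFA1Y overexpression plants of the female background it stood at 362 ± 0.893 CPM, and the other libraries of that background held 0 reads. A hypothesis is that MpVg00470 is the gene introduced in the HSFA1Y overexpression lines. Of 207 V-linked identifiers, 70 of them with reads in Tak-1 controls, 1 reached 5 CPM and was at least 10 times higher in those female libraries than in BC3 control libraries. It was MpVg00470, whose high level there prompted the hypothesis, so the count adds only that no other V-linked identifier passed. By library total, V-linked identifiers together held 604 and 563 CPM in BC3 controls, against 2463 and 2210 in Tak-1 controls. Identifiers already read in BC3 controls had less room to be 10 times higher, so the count says little about them. The line could still differ in another way, since no sequence of the introduced gene was used here.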
